A study of Bacteroides thetaiotaomicron with 10 samples.

How the data were processed

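RNA was sequenced from cultures of Bacteroides thetaiotaomicron VPI-5482 in 5 groups of 2 libraries each. A monoclonal antibody (mAb) or buffer was added in early log phase and cells were collected later in log phase, with the OD600 of each culture recorded. The groups were PBS (the carrier), mAb260.8, mAb225.4, both mAbs together, and control IgA, a mouse IgA that does not bind this bacterium. Ribosomal RNA had been depleted before library preparation. Per the labels, reads were aligned with Bowtie 1.1.0 and differences were computed with DESeq2 in R 3.1.2. The version of DESeq2 and the name of the genome build are not given in the sources used here.

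The deposited files give expected counts per gene, in which a read that matches more than 1 place equally well is split between the places. About 3% of the genes in each file held such fractions, and the values were rounded to whole counts. The files list 4765 genes, all of them coding sequences, under locus tags. Tags stand in place of gene symbols, because the reference table holds 0 of them, so that symbols, coordinates, lengths and GC content were not used here. Product labels in the files stop at the first word, and for 2961 genes (62.1%) that word is hypothetical, putative or conserved. Label words are therefore quoted as they stand and do not identify a protein in full. Lines that count tied and intergenic reads were present in 7 files and not in the other 3, which are PBS replicate 1, mAb260.8 replicate 1 and mAb225.4 replicate 1.

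Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Library sizes were scaled with TMM, and filterByExpr on the groups left 4237 genes to test and 528 untested. A single quasi-likelihood model (glmQLFit, robust, 5 group means) was fitted to all 10 libraries, leaving 5 residual degrees of freedom among the libraries. Each comparison was a two-sided contrast in that model, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. With this common spread, adjusted p-values measure change against the difference between the 2 libraries of a group, pooled over the groups. As no block was fitted, that spread includes any shift shared by replicate number or file format. The common biological coefficient of variation was 0.185. Fold changes are given on the log2 scale with a standard error (SE), first condition minus second. The SE was derived from the test, as the absolute log2 change divided by the square root of the F statistic. Normalised counts (CPM, counts scaled to a common library size) use the TMM library sizes, and log2 CPM used a prior count of 2. Groups of 2 libraries are given as mean ± SD. Among the genes, 58 share an identical count profile with another gene, so their reads were split between copies.

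The 11 comparisons were the 3 mAb conditions against control IgA, the 3 mAb conditions and control IgA against PBS, the mAb conditions among themselves, and the 3 mAb conditions pooled against PBS and control IgA pooled. Comparisons that share a group share its libraries, and so are not independent of each other.

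The comparisons, the tests, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where said otherwise. Named genes were the 10 largest rises and 10 largest falls past the threshold, among genes whose libraries did not overlap between the groups compared. That number applied to the main comparisons, which are the 3 with control IgA as reference, control IgA against PBS and the pooled comparison. The others took 5 rises and 5 falls, and a comparison with no gene past the threshold took the 2 genes of smallest p in each direction. The capsule locus CPS4 and the lipopolysaccharide glycan locus were described in the 3 mAb comparisons with control IgA, with the extreme members of each, and in control IgA against PBS. Runs of neighbouring tags and members of a list could be described as groups. Any other gene named was chosen after its values were seen: this holds for the members of lists given as examples, for BT4615, BT0897 and BT0504 in control IgA against PBS, for BT0504 and BT0897 in mAb260.8 against control IgA, for BT0326 in the pooled comparison, and for the neighbours of BT0357.

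A total of 51 gene lists (capsule loci, glycan-use loci and functional classes searched by product label) were planned. As labels stop at the first word, 11 lists found no member and 5 had 1 to 4 tested members, leaving 35 that were tested with limma's camera. A further 8 lists, built on first words and 1 locus, were added after the files were seen, and adjusted p-values for these 8 are over all lists tested. Camera used an estimated correlation between genes, with Benjamini-Hochberg adjustment over the lists within each comparison. Counts of members that rose or fell use the adjustment over all genes, and counts adjusted over the list alone are given beside the main ones.

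Where a group had 0 reads for a gene, the fold is a lower limit computed against 3 counts over the group. With 1 to 3 reads, the ratio of normalised counts is given with its exact 95% confidence interval. Intervals and floors cover counting error only. Library totals lay between 3697398 and 5121959 counts.

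The procedure was tested on simulated data with known changes in 100 genes of each size. For control IgA against PBS it recovered 49% of changes of 1 log2 unit and 76% of changes of 2 log2 units, with 4.58% of calls false. The simulated mAb260.8 against control IgA comparison recovered 52% and 86%, with 5.48% of calls false. Simulated counts were drawn independently for each gene and library, without an effect shared by replicate number or file format. These shares may therefore not carry over to the real libraries.

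Alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, replicate number as a block, OD600 as a covariate, a preset correlation of 0.01 for the lists, and each library left out in turn. Thinning of all libraries to the lowest total, and a block for the 3 files without summary lines, were added after the data were seen. Counts of genes are without a block unless a block is named. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.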

Results

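Transcript levels were measured by RNA sequencing in Bacteroides thetaiotaomicron, a gut commensal, after contact with antibodies in culture. There were 2 libraries for each of PBS, mAb260.8, mAb225.4, both mAbs and control IgA. Total counts were 5121959 and 4633118 with PBS, 4916140 and 4762341 with mAb260.8, and 5037478 and 3697398 with mAb225.4. With both mAbs they were 3857710 and 4192934, and with control IgA 3936815 and 4429716. The mean OD600 at harvest was 0.554 with PBS, 0.575 with mAb260.8, 0.549 with mAb225.4, 0.624 with both mAbs and 0.584 with control IgA. Within groups, log2 CPM of the 2 libraries correlated across genes with r from 0.966 to 0.987, and genes are not independent replicates.

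Control IgA against PBS asks whether an antibody that does not bind the bacterium leaves its transcripts as the carrier does. BT1884, whose label begins with "cold", rose from 10.3 ± 0.120 CPM with PBS to 371 ± 65.6 CPM with control IgA (SD, n = 2 each), a log2 change of 5.16 (SE 0.27, adjusted p = 2.76e-06). The next 3 tags rose with it: BT1885 by 4.06, BT1886 by 4.03 and BT1887 by 3.32 on the log2 scale. BT0784 (log2 change 3.78) and BT0198 (3.18) rose as well, and all 6 of these genes stayed past the threshold whichever library was left out. All 9 genes of the run BT1528 to BT1536, of which 3 are labelled two-component and 3 ABC, rose by 0.71 to 2.58, and BT1532 (ABC) rose most.

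Some genes for protein folding fell with control IgA. Of 6 tested genes on the chaperone and heat shock list, 3 fell and 0 rose: the chaperonin BT1829 (log2 change -2.19, SE 0.44, adjusted p = 0.0093), the co-chaperonin BT1830 (-1.52) and BT1244 (-1.03). Adjusted over the list alone, 3 fell, and the list itself had an adjusted p = 0.27 with an estimated correlation. BT1829 lost the threshold without PBS replicate 1 (adjusted p = 0.0542), control IgA replicate 1 (0.0811) or control IgA replicate 2 (0.115), and BT1244 lost it without these same libraries, while BT1830 kept it. Outside the list, BT0897 (label "heat") fell from 1491 ± 172 to 425 ± 36.3 CPM (SD, n = 2 each), and BT4615 (label "molecular") fell from 1639 ± 276 to 519 ± 36.9 CPM, both whichever library was left out. On the list of oxidative stress defence, 4 of 13 genes fell and 1 rose. Those that fell were 3 ferritins (iron storage), among them BT1107 (-1.22), and the catalase BT1971 (-0.69), which breaks down hydrogen peroxide. Adjusted over the list alone these counts were also 4 and 1, and the list had an adjusted p = 0.351. BT1107 kept the threshold whichever library was left out, and BT1971 lost it without either control IgA replicate or PBS replicate 2. The receptor gene BT0504 (label "TonB-dependent", a class that takes up nutrients through the outer membrane) fell by 1.72 on the log2 scale.

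Some genes at loci for surface polysaccharides rose with control IgA. At the capsule locus CPS1, 13 of 28 tested genes rose and 0 fell, among them BT0390 (log2 change 1.57) and BT0396 (1.50). At CPS4, the locus of the capsule known to be bound by mAb225.4, 13 of 21 rose and 0 fell, with BT1338 at 1.25 and BT1354 at 1.26, the latter lost without either control IgA replicate or PBS replicate 2. CPS3 had 7 of 21 genes that rose, with BT0609 at 1.42, and CPS2 had 1 of 21. At the lipopolysaccharide glycan locus 5 of 19 rose, with BT3368 at 1.01. With OD600 as a covariate 7 genes rose at CPS4 and 3 at the lipopolysaccharide locus. Adjusted over the list alone, 15 genes rose at CPS1, 15 at CPS4, 13 at CPS3 (where 2 fell), 0 at CPS2 and 6 at the lipopolysaccharide locus. Each of these 5 lists had an adjusted p = 0.183 with an estimated correlation, so none of them passed as a group. The high-mannose N-glycan locus, for use of host glycans, had 5 of 12 genes that rose (5 adjusted over the list alone, list adjusted p = 0.384), with BT3983 at 1.44. At the yeast mannan loci 6 of 33 rose (6 adjusted over the list alone, list adjusted p = 0.183), with BT3787 at 1.41.

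The comparison of control IgA with PBS had 713 genes past the threshold, 359 higher and 354 lower, of which 125 rose and 122 fell at least 2-fold. Further genes with large changes had few reads. BT1064 had 0 reads with PBS and 25 with control IgA, at least 10.2-fold higher, and BT3417 had 17 and 0, at least 4.63-fold lower. BT4424 (label "sorbitol") had 38 reads with PBS and 2 with control IgA, a ratio of 15.5 (95% confidence interval 4.01 to 133). Other rises were BT2804 (ribokinase, log2 change 3.34), BT3420 (3.34) and BT0357 (3.23), of which BT0357 lost the threshold without PBS replicate 1 (adjusted p = 0.085), PBS replicate 2 (0.10) or control IgA replicate 2 (0.11). Other falls were BT0925 (label "ABC", -2.91), BT3471 (-2.79), BT4150 (-2.74), BT3737 (-2.57), BT0439 (-2.40), BT3095 (-2.25), BT0924 (-2.25) and BT1212 (-2.20). Of the genes in this paragraph, BT3737 and BT0924 stayed past the threshold whichever library was left out, and each other lost it without at least 1. The count fell to 383 without PBS replicate 1, 212 without PBS replicate 2, 232 without control IgA replicate 1 and 146 without control IgA replicate 2. With OD600 as a covariate it was 396.

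**Figure D1:**
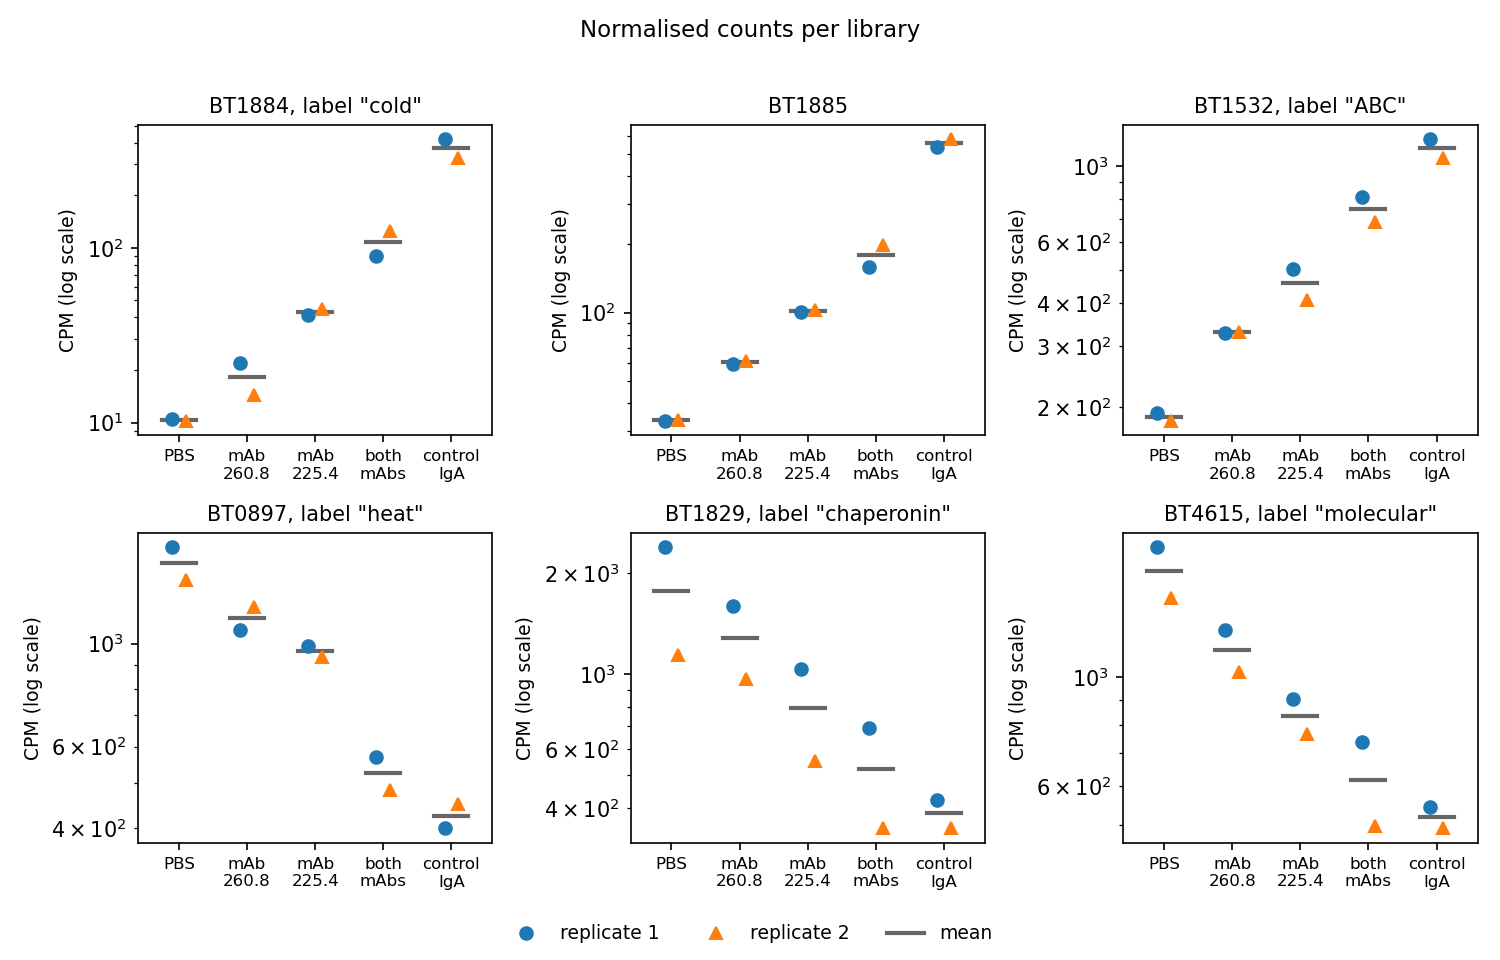
CPM on a log scale for 6 genes in each of the 10 libraries, by group; circles are replicate 1, triangles replicate 2 and grey bars the mean of the 2. BT1884 had a mean of 10.3 CPM with PBS, 18.2 with mAb260.8, 43.1 with mAb225.4, 108 with both mAbs and 371 with control IgA, while BT0897 had means of 1491, 1135, 962, 528 and 425 CPM in these groups.

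The comparison of mAb260.8 with control IgA sets a binding antibody against a non-binding one. Against PBS, 713 genes passed with control IgA and 4 with mAb260.8. A rise or fall here may thus be a change with control IgA seen with the opposite sign, and cannot be credited to binding. BT1884, for example, had 10.3 CPM with PBS. The same limit holds for mAb225.4 and both mAbs against control IgA, as 9 and 29 genes passed with these against PBS. With replicate number as a block, 17 of 21 CPS4 genes rose with control IgA against PBS and 0 changed with mAb260.8. In that fit 8 rose and 1 fell with mAb225.4 against PBS, and 2 rose with both mAbs. At the lipopolysaccharide locus 9 of 19 rose with control IgA, 0 changed with mAb260.8, 9 rose with mAb225.4 and 4 with both mAbs. Falls at these loci against control IgA may thus mirror the rise with control IgA. BT1884 was at 18.2 ± 5.39 CPM with mAb260.8 against 371 ± 65.6 CPM with control IgA (SD, n = 2 each), a log2 change of -4.34 (SE 0.26, adjusted p = 9.49e-06). BT1885 (-3.21), BT0784 (-3.15), BT1886 (-2.93), BT1887 (-2.93), BT0198 (-2.61), BT4432 (-2.25) and BT1532 (ABC, -1.77) fell as well, and 8 of 9 genes of the run BT1528 to BT1536 fell. BT0357 had 2 reads over the mAb260.8 libraries and 2234 over the control IgA libraries, a ratio of 1331 (95% confidence interval 368 to 10996), and BT0357 kept the threshold whichever library was left out. BT2170 rose by 1.76 (SE 0.17, adjusted p = 2.78e-04), BT0504 by 1.49 and BT0897 by 1.42 on the log2 scale.

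Some genes for protein folding and iron storage were higher with mAb260.8 than with control IgA. On the chaperone list 2 of 6 rose (3 adjusted over the list alone; list adjusted p = 0.425 with an estimated correlation), namely BT1829 by 1.73 and BT1830 by 1.08, both lost without at least 1 library. On the oxidative stress list 2 of 13 rose (3 adjusted over the list alone; list adjusted p = 0.425), both ferritins, with BT1107 at 1.32. At CPS4, without a block, 2 of 21 genes fell and 0 rose (11 fell adjusted over the list alone, list adjusted p = 0.425), and 7 fell with DESeq2. The median was -0.53, and the extreme values were BT1338 at -0.93 (adjusted p = 0.0155) and BT1357 at 0.19 (adjusted p = 0.836). At the lipopolysaccharide locus 2 of 19 fell (2 adjusted over the list alone; list adjusted p = 0.425), the median being -0.26. The extreme values were BT3377 at -0.76 (adjusted p = 0.121, and 0.0058 with file format as a block) and BT3379 at 0.09. At CPS1 4 of 28 genes fell (10 adjusted over the list alone; list adjusted p = 0.425).

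Between mAb260.8 and control IgA 371 genes passed, 196 higher and 175 lower, with 64 and 57 of them changed at least 2-fold. Further rises were BT3417 (20 reads against 0, at least 5.60-fold higher), BT0925 (2.56), BT3737 (2.46), BT3471 (2.44), BT3095 (2.25), BT0924 (1.87), BT3908 (1.61) and BT3734 (label "oxidoreductase", 1.56), and a further fall was BT4639 (-2.38). These 9 genes, BT1829, BT1830 and BT1338 each lost the threshold without at least 1 library. The count fell to 68 without mAb260.8 replicate 1, 83 without mAb260.8 replicate 2, 65 without control IgA replicate 1 and 40 without control IgA replicate 2.

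For mAb225.4 against control IgA, the falls again included BT1884, from 371 ± 65.6 to 43.1 ± 2.41 CPM (SD, n = 2 each; log2 change -3.11, SE 0.24, adjusted p = 1.46e-04). BT1885 (-2.46), BT1886 (-2.33), BT0198 (-2.18) and BT0784 (-2.14) fell, and these 5 genes stayed past the threshold whichever library was left out. In the run BT1528 to BT1536 5 of 9 genes fell, BT1532 most (-1.30). BT0504, the TonB-dependent gene, rose 2.14-fold (adjusted p = 0.0022), and BT0897 rose by 1.18 on the log2 scale. At CPS4, without a block, 0 of 21 genes passed (0 adjusted over the list alone; list adjusted p = 0.605), with a median of -0.24, BT1339 lowest at -0.76 (adjusted p = 0.259, and 0.0209 with file format as a block) and BT1345 highest at 0.22. At the lipopolysaccharide locus 0 of 19 passed (0 adjusted over the list alone; list adjusted p = 0.957). Its median was 0.03, while its mean (-0.02) and its test pointed down, with BT3378 at -0.37 (adjusted p = 0.698) and BT3379 at 0.36 (adjusted p = 0.395) as the extremes.

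In all, 48 genes passed between mAb225.4 and control IgA, 21 higher and 27 lower. Other rises were BT3737 (2.15), BT2170 (1.46), BT3734 (1.32), BT2068 (label "3-oxo-5-alpha-steroid", 1.22), BT1123 (label "transcriptional", 1.20), BT2658 (1.19), BT1108 (1.07) and BT0962 (label "aldo/keto", 0.98). Other falls were BT1887 (-1.84), BT2243 (-1.78), BT4311 (label "glucose/galactose", -1.54), BT4432 (-1.44) and BT0530 (label "anthranilate", a word from tryptophan synthesis, -1.31). Each of these 13 genes, and BT0897, lost the threshold without at least 1 library. The count was 16 without mAb225.4 replicate 1, 14 without mAb225.4 replicate 2, 10 without control IgA replicate 1 and 12 without control IgA replicate 2. It was 21 with OD600 as a covariate and 162 with DESeq2.

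With both mAbs against control IgA 6 genes passed without a block, 3 in each direction. With a block for replicate number the count was 332, and with one for file format 108. BT1885 fell from 560 ± 29.2 to 179 ± 27.2 CPM (SD, n = 2 each; log2 change -1.65, SE 0.15, adjusted p = 0.0015), and BT1884 (-1.78) and BT0198 (-1.64) fell. BT2170 (1.28), BT0504 (1.03) and BT0962 (0.86) rose. At CPS4, without a block, 0 of 21 genes passed (0 adjusted over the list alone; median -0.40, list adjusted p = 0.366), from BT1354 at -0.81 (adjusted p = 0.258) to BT1357 at 0.84 (adjusted p = 0.395). At the lipopolysaccharide locus, 0 of 19 passed (0 adjusted over the list alone; median -0.27, list adjusted p = 0.37), from BT3378 at -0.56 to BT3364 at 0.11. BT1885 stayed past the threshold whichever library was left out and with OD600 as a covariate, and each of the other 5 genes lost it under both kinds of change. The count was 1 without both-mAbs replicate 1, control IgA replicate 1 or control IgA replicate 2, 1 with OD600 as a covariate and 79 with DESeq2.

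Against PBS, mAb260.8 was followed by a fall of 4 genes and a rise of 0. BT0326 fell from 664 ± 5.82 to 268 ± 26.4 CPM (SD, n = 2 each; log2 change -1.31, SE 0.14, adjusted p = 0.0051). BT0325 (-1.21), BT2494 (label "ABC", -1.04) and BT0323 (-0.99) were the others. None of the 35 planned lists passed, the lowest adjusted p being 0.0839 for the yeast mannan loci. The count was 0 without PBS replicate 2, mAb260.8 replicate 1 or mAb260.8 replicate 2, and 17 with DESeq2.

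Against PBS, mAb225.4 was followed by a rise of 9 genes and a fall of 0. BT1884 rose from 10.3 ± 0.120 to 43.1 ± 2.41 CPM (SD, n = 2 each; log2 change 2.05, SE 0.26, adjusted p = 0.0068). BT1886 (1.70), BT0784 (1.64), BT1885 (1.61) and BT2500 (1.49) rose, and 4 genes of the run BT1528 to BT1536 made up the rest. Each of the 5 named genes lost the threshold without at least 1 library. The count was 3 without PBS replicate 1 and 0 without PBS replicate 2. It was 6 without mAb225.4 replicate 1, 6 without mAb225.4 replicate 2, and 69 with DESeq2.

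With both mAbs against PBS, 29 genes passed, 16 higher and 13 lower. BT1884 rose from 10.3 ± 0.120 to 108 ± 24.9 CPM (SD, n = 2 each; log2 change 3.38, SE 0.26, adjusted p = 6.82e-05). BT1886 (2.66), BT1885 (2.42), BT0784 (2.25) and BT1532 (2.00) rose, and 8 of 9 genes of the run BT1528 to BT1536 rose. The co-chaperonin BT1830 (-1.66), BT0897 (-1.50), BT4615 (-1.41), BT0565 (-1.35) and BT0326 (-1.10) fell, as did all 4 genes from BT0323 to BT0326. BT1830, BT4615 and BT0565 lost the threshold without at least 1 library. With OD600 as a covariate BT0784 and BT0326 also lost it and the count was 10. It was 19 without PBS replicate 1, 15 without PBS replicate 2, 18 without both-mAbs replicate 1, 13 without both-mAbs replicate 2, and 65 with DESeq2.

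Adding mAb225.4 to mAb260.8 was examined by comparing both mAbs with mAb260.8, where 9 genes were higher and 1 lower. BT0357 had 2 reads with mAb260.8 and 1867 with both mAbs, a ratio of 1122 (95% confidence interval 310 to 9273; adjusted p = 0.0058). BT1884 rose from 18.2 ± 5.39 to 108 ± 24.9 CPM (SD, n = 2 each; log2 change 2.56, SE 0.25, adjusted p = 0.0016). BT0784 (1.62), BT1886 (1.56) and BT1885 (1.56) rose, as did 4 genes of the run BT1528 to BT1536, and BT0897 fell by 1.11 on the log2 scale. BT1884 stayed past the threshold whichever library was left out, and the other 5 named genes lost it without at least 1. The count was 1 without mAb260.8 replicate 1, 2 without mAb260.8 replicate 2, 3 without both-mAbs replicate 1 and 4 without both-mAbs replicate 2. It was 3 with OD600 as a covariate and 20 with DESeq2.

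Between mAb225.4 and mAb260.8, edgeR without a block called 0 genes, with 304 genes at an unadjusted p under 0.05, and DESeq2 called 12. BT0357 had 2 reads with mAb260.8 and 836 with mAb225.4, a ratio of 460 (95% confidence interval 127 to 3804; edgeR adjusted p = 0.0637). BT0326 had a log2 difference of 0.91 (adjusted p = 0.072). In the other direction BT1450 (label "propionyl-CoA") had -1.06 (adjusted p = 0.439) and BT1573 -0.66 (adjusted p = 0.508). Between both mAbs and mAb225.4, edgeR without a block also called 0 genes, with 247 at an unadjusted p under 0.05, and DESeq2 called 4. The genes of smallest p were BT1884 at 1.33, BT1885 at 0.81, BT0897 at -0.87 and BT0326 at -0.71, each with an adjusted p = 0.302. Without mAb225.4 replicate 1, and with OD600 as a covariate, 1 gene passed between mAb225.4 and mAb260.8, which was BT0357.

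The 6 libraries with a binding mAb were compared with the 4 libraries of PBS and control IgA. BT0326 was the 1 gene past the threshold, with a log2 change of -0.76 (SE 0.085, adjusted p = 0.011), and 268 genes had an unadjusted p under 0.05. The libraries of the pooled groups overlapped for BT0326: the 4 libraries with mAb260.8 lay between 249 and 311 CPM, and the other 6, mAb225.4 included, between 464 and 668 CPM. DESeq2 called 13 genes, and the count was 3 with RLE scaling and 4 without a filter. It was 0 without either PBS replicate, either control IgA replicate, either both-mAbs replicate or mAb260.8 replicate 2.

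**Figure D2:**
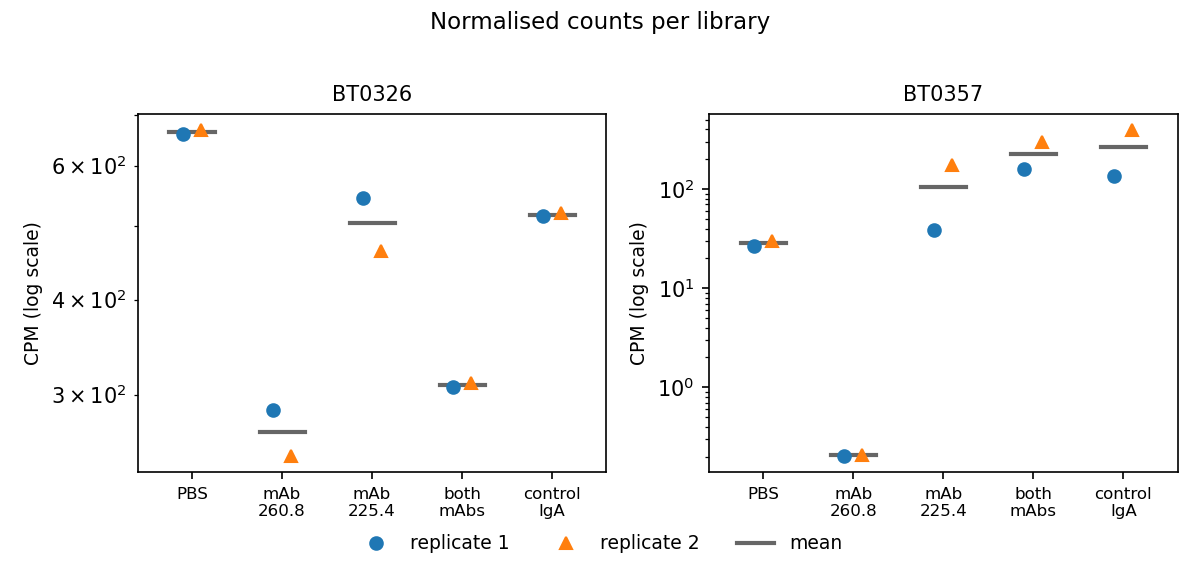
CPM on a log scale for BT0326 and BT0357 in each of the 10 libraries, by group; circles are replicate 1, triangles replicate 2 and grey bars the mean of the 2. BT0326 lay between 249 and 311 CPM in the 4 libraries given mAb260.8 and between 464 and 668 CPM in the other 6, and BT0357 averaged 0.206 CPM with mAb260.8, 28.4 with PBS and 266 with control IgA.

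**Figure D3:**
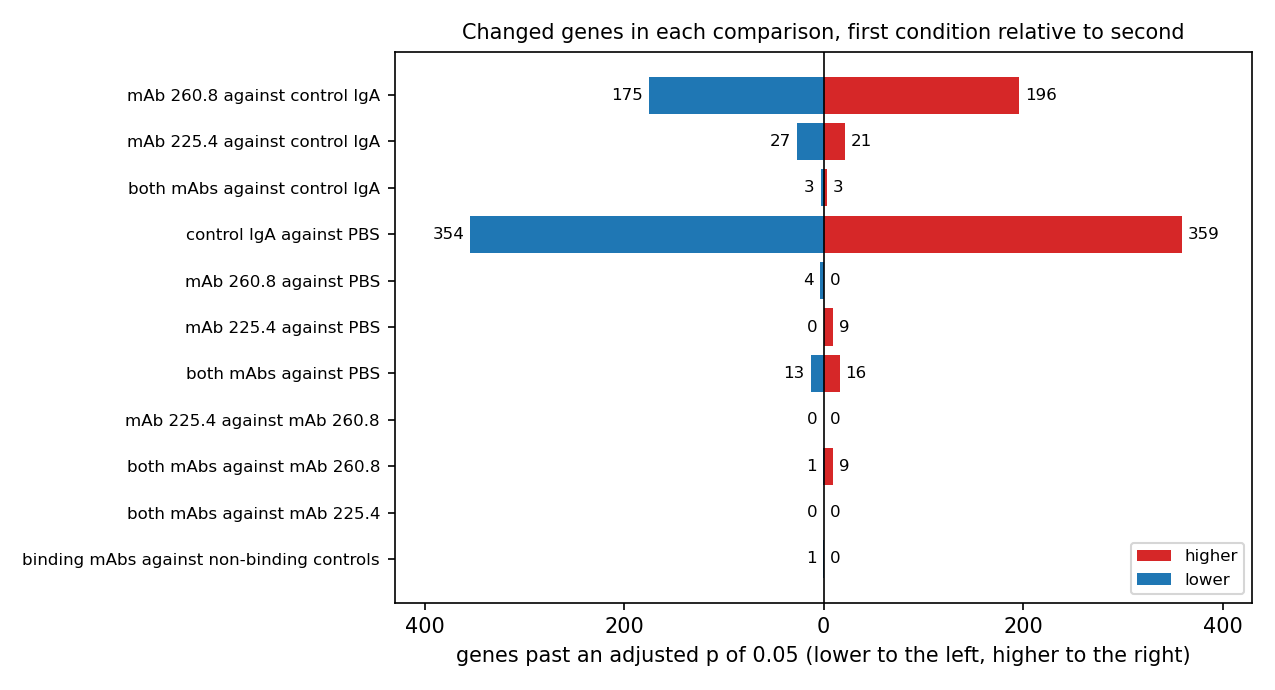
Number of genes past an adjusted p of 0.05 in each of the 11 comparisons, higher in the first condition to the right and lower to the left. Control IgA against PBS had 359 higher and 354 lower, mAb260.8 against control IgA 196 and 175, and mAb225.4 against mAb260.8 had 0 in each direction.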

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

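Tests of the OD600, of library depth, of the order of the tubes, of the depth behind BT0357 and of file format as a block were chosen after the results were seen, while the test of shared reads was set before its result was seen.

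The effects of 2 conditions, each relative to PBS, differed by a direct test in 4 pairs. Between mAb260.8 and control IgA 371 genes differed, between mAb225.4 and control IgA 48, between both mAbs and control IgA 6, and between both mAbs and mAb260.8 10. Between both mAbs and mAb260.8, BT0357 had a fitted log2 difference of 9.92, which rests on 2 reads in the mAb260.8 libraries and so depends on the prior count (9.42 with file format as a block, adjusted p = 0.225). Groups of 2 libraries are too small for a test of single outlying libraries.

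Control IgA against PBS gave more changed genes, 713, than any of the other 10 comparisons, and BT1884 to BT1887 were among its 10 largest rises. On an axis from PBS (0) to control IgA (1), with direction and position taken from different replicates, mAb260.8 lay at 0.15 ± 0.02, mAb225.4 at 0.51 ± 0.05 and both mAbs at 0.52 ± 0.13 (SD, n = 2 each). Each library was placed relative to the PBS and control IgA libraries of its own replicate number. The scores thus assume pairing by number, for which the rule was met by 8 of 10 pairs of groups and so was not passed. OD600 at harvest as the whole source is argued against by the both-mAbs libraries, which had the highest mean OD600 (0.624) and a score of 0.515. A single reading does not settle growth stage, and a part played by OD600 stays open. With OD600 as a covariate 396 genes passed, of which 370 were among the 713. Unequal library depth is argued against by the 672 of 713 genes still called after thinning. Tube order, if the last digit of the sample names stands for it, stays open. That digit rises with the group and is the same for a group in both replicates, so that order and antibody cannot be told apart. Of the pairs of mAb libraries, 5 of 6 were in that order (one-sided exact p = 0.139, smallest possible 0.0278). This test bears on the order of the mAb groups alone, whatever its source. An effect of the antibodies themselves, including any other component of each antibody preparation, may also account for the pattern and was not tested.

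BT0357 had 1 read in each mAb260.8 library, against 26.7 to 396 CPM in the other 8 libraries. Depth is argued against, since 259 reads were expected in the mAb260.8 libraries at the lowest level seen elsewhere. Reads shared with another copy stay open, because 7 libraries gave this gene a fraction of a read. The neighbouring gene BT0356 had 165 to 309 reads and the transposase BT0358 had 37 to 79 reads in every library. The antibody is another open explanation, although the both-mAbs libraries also received mAb260.8 and had 158 and 296 CPM, and a change in the DNA of those cultures was not tested.

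BT0326 lay between 249 and 311 CPM in the 4 libraries given mAb260.8 and between 464 and 668 CPM in the other 6. Against PBS it fell with mAb260.8 (log2 change -1.31, adjusted p = 0.0051) and with both mAbs (-1.10, SE 0.13, adjusted p = 0.0019), and 3 of 4 and 4 of 4 genes from BT0323 to BT0326 passed (3 and 0 against control IgA). With mAb260.8 it no longer passed without PBS replicate 2 or without either mAb260.8 library, and with both mAbs it did not pass with OD600 as a covariate (-0.87, SE 0.19, adjusted p = 0.24). Against PBS, the 4 genes from BT0323 to BT0326 were also lower with mAb225.4 (-0.58 to -0.19, 0 passed). With control IgA they lay at -0.58 to -0.15, and 1 passed. A level below that with PBS was thus also seen without mAb260.8, to a smaller extent. An effect of mAb260.8, which the design names, stays open, and the source of the fall in BT0326 was not tested further.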

How the results depend on the processing

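Thinning, file format as a block and the lists by first word were chosen after the data were seen. The alternatives were applied to 143 named gene values, and those kept their direction and side of the threshold in 143 of 143 cases with RLE scaling, 140 of 143 without a filter, 121 of 128 with DESeq2 (7 newly passed), 133 of 141 after thinning, 135 of 143 with file format as a block (5 newly passed), 132 of 143 with replicate number as a block (11 newly passed) and 105 of 143 with OD600 as a covariate (36 no longer passed). With libraries left out, 354 of 578 kept both, 217 no longer passed and 1 newly passed. A lone library is then assumed to vary like the other groups, and such a fit has fewer libraries. Low depth limits genes with few reads, for which folds are bounds or have wide intervals. A fit that keeps ribosomal and transfer RNA genes was not run, because the files list coding sequences.

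DESeq2 gave 162 genes for mAb225.4 and 79 for both mAbs against control IgA, 17 for mAb260.8, 69 for mAb225.4 and 65 for both mAbs against PBS. It gave 12 for mAb225.4 and 20 for both mAbs against mAb260.8, 4 for both mAbs against mAb225.4 and 13 for the pooled comparison. With OD600 as a covariate there were 21 for mAb225.4 and 1 for both mAbs against control IgA, 396 for control IgA and 10 for both mAbs against PBS, and 1 for mAb225.4 and 3 for both mAbs against mAb260.8. The pooled count of 1 became 3 with RLE scaling, 4 without a filter and 3 after thinning. No list by comparison pair passed under any scaling, block or covariate, with the added lists or with a library left out, and 54 of 385 pairs passed with a preset correlation of 0.01. In the planned pair without a shared library, mAb260.8 against PBS with mAb225.4 against control IgA, 0 genes were called in the same direction. In the second, BT0323 to BT0326 (3 called in the first) lay at -0.062 to -0.00085. Chance would give 0.0255, and the correlation across genes was -0.0831. With the controls swapped the number was also 0 (0.416 by chance, correlation -0.342). All 9 genes called with mAb225.4 against PBS were called with opposite sign, as a rise with control IgA would give. Why the counts moved between settings was not tested.

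Leaving out 1 library gave 40 to 83 genes for mAb260.8, 10 to 16 for mAb225.4 and 1 to 6 for both mAbs against control IgA. Against PBS it gave 146 to 383 for control IgA, 0 to 6 for mAb260.8, 0 to 6 for mAb225.4 and 13 to 19 for both mAbs. The range was 0 to 1 for mAb225.4 and 1 to 4 for both mAbs against mAb260.8, 0 for both mAbs against mAb225.4, and 0 to 1 for the pooled comparison. Directions reversed for the CPS4 and lipopolysaccharide locus genes named next, which passed in no setting. Against control IgA, BT1357 in mAb260.8 ran from -0.19 without control IgA replicate 2 to 0.66 without control IgA replicate 1, and BT3379 in mAb260.8 from -0.080 without mAb260.8 replicate 2 to 0.21 without mAb260.8 replicate 1. In mAb225.4, BT1345 ran from -0.28 without mAb225.4 replicate 2 to 0.58 without mAb225.4 replicate 1. BT3378 ran from -0.90 without mAb225.4 replicate 2 to 0.039 without mAb225.4 replicate 1, and was 0.092 with OD600 as a covariate. With both mAbs BT1357 ran from -0.19 without both-mAbs replicate 2 to 1.42 without both-mAbs replicate 1, and BT3364 from -0.036 without control IgA replicate 2 to 0.23 without control IgA replicate 1. The cause was not tested.

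The rule set beforehand for pairing by replicate number, a correlation of deviations above 0.1 in all 10 pairs of groups, was met by 8 of them. All 10 correlations were positive (0.05 to 0.34), and the second principal component parted all 5 replicate 1 from all 5 replicate 2 libraries. These are hints from the data, not the design, that same-numbered libraries share a source of variation unnamed in the labels. With replicate number as a block, counts were 1025, 480 and 332 for mAb260.8, mAb225.4 and both mAbs against control IgA, and 1238, 20, 262 and 137 for control IgA, mAb260.8, mAb225.4 and both mAbs against PBS. They were 49 for mAb225.4 (0 without the block) and 34 for both mAbs against mAb260.8, 10 for both mAbs against mAb225.4 (0), and 33 for the pooled comparison. Against control IgA, 12 of 21 CPS4 genes fell with mAb260.8 (2 without the block), 3 with mAb225.4 (0) and 4 with both mAbs (0), and 7 of 19 genes of the lipopolysaccharide locus fell with mAb260.8 (2). Among them BT3377 with mAb260.8 (-0.76, adjusted p = 0.017), BT1339 with mAb225.4 (-0.77, adjusted p = 0.026) and BT1354 with both mAbs (-0.80, adjusted p = 0.029) newly passed. For the pooled count of 1, 13 of 100 groupings of the libraries (with the real one) gave as many genes, so chance is not excluded. The highest other grouping gave 234, others 227 and 34, which points to a structure of the samples. These 3 were among the 5 groupings that took the 3 files without summary lines as controls, and the other 2 gave 0. Other groupings with 4 replicate 1 libraries as controls gave 1, and the source of the structure was not identified.

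With file format (these 3 files against the other 7) as a block, counts were 692, 350 and 108 for mAb260.8, mAb225.4 and both mAbs against control IgA, and 15, 81 and 97 for mAb260.8, mAb225.4 and both mAbs against PBS. They were 5 and 16 for mAb225.4 and both mAbs against mAb260.8, 9 for both mAbs against mAb225.4, and 10 for the pooled comparison. Against control IgA, 10 CPS4 genes fell with mAb260.8, 1 with mAb225.4 and 1 with both mAbs, and 4 genes of the lipopolysaccharide locus fell with mAb260.8. The 3 values that no longer passed were BT3471 in mAb260.8 against control IgA (2.26) and BT0357 in control IgA (2.56, against PBS) and both mAbs (9.42, against mAb260.8). The cause was not tested.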

Other observations

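The lists built on first words and the overlaps of comparisons were chosen after the results were seen. Of the ribosomal protein genes (label 30S or 50S), 26 of 52 rose and 0 fell with control IgA against PBS (31 rose adjusted over the list alone), with a median log2 change of 0.53, BT2163 at 1.04 and BT1271 at 1.09. The list had an adjusted p = 0.169 with an estimated correlation, and BT1271 lost the threshold without control IgA replicate 1 or PBS replicate 2. With mAb260.8 against control IgA 13 of 52 fell (24 adjusted over the list alone; list adjusted p = 0.32). Genes of the V-type ATPase, an ion pump, fell with control IgA against PBS in 4 of 5 cases (4 adjusted over the list alone; list adjusted p = 0.169), with BT1298 at -0.93 and BT1296 at -0.80. With mAb260.8 against control IgA 4 of 5 rose (5 adjusted over the list alone; list adjusted p = 0.32), with BT1298 at 0.92. BT1296 lost the threshold without control IgA replicate 1 against PBS and without each of the 4 libraries in the comparison with mAb260.8, where BT1298 lost it without control IgA replicate 2.

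Among genes labelled as glycoside hydrolases, which break down polysaccharides, 8 of 86 fell and 1 rose with control IgA against PBS (8 and 1 adjusted over the list alone; list adjusted p = 0.384). Over all genes 354 of 4237 fell, so that the share that fell on this list was near the share over all genes. The alpha-galactosidase BT4157 had a log2 change of -1.45 and the alpha-xylosidase BT3085 -1.09, while the alpha-xylosidase BT3169 rose by 0.82. Each of these 3 lost the threshold without at least 1 library. At the capsule loci CPS5 and CPS8, 0 of 15 and 0 of 34 genes passed (edgeR), and their lists had adjusted p = 0.5 and 0.992. At the starch use locus 0 of 8 passed (list adjusted p = 0.992).

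Control IgA against PBS and both mAbs against mAb260.8 share no library. Of the 713 genes that changed in the first, 661 (92.7%) had the same sign in the second, and 9 genes were higher in both where independent lists would share 0.763. Across genes the Pearson correlation of their log2 changes was 0.38, and genes are not independent replicates. With mAb225.4 against mAb260.8 the share of the same sign was 87.1%, and with both mAbs against mAb225.4 it was 53.3%. In each of these comparisons the first condition also has the higher last digit in its sample names. The shares therefore do not tell tube order from antibody.

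PBS replicate 2 had 1132 intergenic reads, and the other 6 libraries with such a line had 199 to 430. The first principal component held 28.9% of the variance and the second 19.2%, with all 5 replicate 1 libraries positive and all 5 replicate 2 libraries negative on the second.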
